A study of Sus scrofa with 11 samples.

How the data were processed

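RNA was measured in 11 libraries of pig liver: 2 labelled as controls at day 0, and 3 at each of 20, 30 and 40 Gy of hepatic irradiation, all labelled day 35. The labels name liver as the tissue, hepatocyte as the cell type and wild type as the genotype. Total RNA was extracted with Trizol, libraries were made with a TruSeq RNA kit, and paired-end reads of 150 bp were read on a HiSeq instrument, per the labels' protocols. Whether the kit and the counting kept the strand is not given in the sources used here, so reads of overlapping genes on opposite strands may be mixed.

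The authors deposited 1 table of FPKM (fragments per kilobase of transcript and per 1e6 mapped fragments) with 12505 genes and 11 value columns, each of which carries the name of 1 library. HISAT2, Cufflinks and HTSeq are named in the submitters' processing notes, without a role or an order. The same notes name the pig build Sscrofa11.1 and the mouse build mm10, and the gene IDs of the table are those of pig. The versions of these tools, the annotation and any filter on the genes are not given in the sources used here.

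FPKM divides by gene length and by the total of each library, so a library in which a few genes take much of the RNA has lower values for all others. The deposited FPKM of the measured genes summed to between 520839 and 949840 per library. The low values were searched for the whole-read steps that would give the depth, and none shared by all genes were found, so the depth of each library is unknown. Neither counting intervals nor detection limits can therefore be given, and precision was judged from the spread between libraries. A value of exactly 0 can be a failed estimate and is reported as listed at 0. Reads shared between near-identical copies may be split in ways that the table does not show, which makes metallothioneins, cytochromes P450, sulfotransferases and hemoglobins uncertain, as are genes that overlap a neighbour.

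Of the 12505 IDs, 10561 were paired with a symbol through a table of gene names and 1944 were not. Coordinates are those of the Sscrofa11.1 gene table, matched by symbol, and give the whole gene. SLC7A11, FTH1, STAB2 and VWF are not analysed here. All 11 columns were mapped to samples by name, and 29 genes at 0 in every library were left out.

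Values were analysed as log2(FPKM + 1), so a fold change is on that scale and understates the change of genes with low values. Genes with at least 1 FPKM in at least 2 libraries were tested, which left 11644 genes. This filter was set after the table had been looked at and before the first test. A linear model with 4 group means was fitted to all 11 libraries in limma 3.58.1 (R 4.3.3), with moderated variances that follow the mean (eBayes with trend) and 7 residual degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. The comparisons were each dose against control, the mean of the 3 dose groups against control, each pair of doses, any difference among the 4 groups, and a linear trend. The trend was fitted to the 9 irradiated libraries with dose as a number, also with 7 residual degrees of freedom, and its slope is given per 10 Gy. Its own filter, the same minimum applied to those 9 libraries, left 11526 genes and was added after a first fit of the trend had been seen. The comparisons, the tests, the gene lists and the rule for named genes were fixed before the data were examined.

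Gene lists for liver functions, stress responses, injury and cell types were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 37 lists (36 in the trend, where erythroid genes had under 4 measured members). Camera asks whether the genes of a list moved more in one direction than the other genes did. It was repeated with a correlation estimated for each list, and fry asked whether the genes of a list moved on balance one way, without comparing them with other genes. The lists covered ferroptosis drivers and suppressors, iron handling, p53 targets, NRF2 targets, the unfolded protein and integrated stress responses, hypoxia, cell cycle, senescence, extracellular matrix, coagulation, secreted plasma proteins, acute phase and complement. They also covered cytochromes P450, bile acids, the urea cycle, fatty acid oxidation, cholesterol synthesis, lipogenesis, gluconeogenesis, pericentral and periportal hepatocytes, interferon response, antigen presentation, fetal liver, the circadian clock and immediate early genes. Cell types were stellate cells, sinusoidal and vascular endothelium, macrophages, neutrophils, T and NK cells, B and plasma cells, bile duct cells and erythroid cells. For each list the number of members called is given over all genes tested and adjusted over the list alone.

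Named genes had a symbol, an adjusted p under 0.05, a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups. From these came the 10 largest rises and 10 largest falls of all irradiated libraries against control, and the 5 of each kind for every single dose, for each pair of doses and for the trend. Where no gene of a comparison passed, the 5 with the smallest unadjusted p were named. Up to 4 members of a described list were named as examples, first among those past the threshold by size of change, then by mean level. GPX4, ACSL4, TFRC, FTL, HMOX1, PTGS2, CDKN1A, MDM2, ALB and COL1A1 were named in any case.

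Libraries were compared by the robust standard deviation of the log2 ratio over 6562 genes with a mean of at least 5 FPKM. The overlap of calls between doses was set against 50 simulations of unchanged groups that shared the same controls, and against the overlap of independent lists. The steps were tested on simulated data built from the real means and spreads. For 40 Gy against control, 42%, 90%, 96% and 100% of 50 genes each were recovered at log2 changes of 1, 2, 3 and 4, and 14 of 11444 unchanged genes were called. For the trend, the shares were 60%, 96%, 98% and 100%, with 16 of 11444 unchanged genes called. Camera called the 1 shifted list and 0 of 30 others. Means and spreads hold no correlated genes or near-identical libraries, so the rates may differ for the real calls.

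Alternatives were no filter, a mean of at least 5 FPKM, an absolute log2 change of at least 1, pseudocounts of 0.1 and 0.01, median-of-ratios scaling, quantile normalization, robust variances, sample quality weights, only the libraries of the groups compared, the replicate number as a block, and leaving out each library in turn. After the data had been seen, 3 settings were added for near-identical libraries: 30Gy-1 and 30Gy-2 averaged into 1, 20Gy-3 and 30Gy-3 left out, and both. Alternatives planned for counts were not run, since the table holds FPKM. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.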

Results

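Pig liver was sampled 35 days after hepatic irradiation with 20, 30 or 40 Gy, with 3 libraries per dose, and set against 2 control libraries labelled day 0. The title of the series names veno-occlusive liver disease, in which small vessels of the liver become blocked, and ferroptosis, an iron-dependent cell death driven by lipid peroxidation. The comparisons therefore ask which liver transcripts differed at each dose, and how the genes of ferroptosis stood among them. All irradiated libraries come from day 35, so dose and elapsed time cannot be separated against control, whereas the doses can be compared with each other at the same day. Nothing in the labels says that the libraries come from separate animals, so p-values measure the spread between libraries, which may be technical. Between 10236 and 10866 genes per library reached 1 FPKM, and the depth is unknown. Levels are FPKM as mean ± SD, with n = 2 in control, n = 3 at 20 Gy, n = 2 at 30 Gy and n = 3 at 40 Gy. The n of 30 Gy counts a near-identical pair of libraries as 1, whereas the SE and p of the fit treat its members as separate. Changes are on the log2(FPKM + 1) scale of the fit to all 11 libraries, with the SE and the Benjamini-Hochberg adjusted p of limma. A range beside an adjusted p is that over the alternatives.

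Most libraries resembled others of their group, with exceptions at 20, 30 and 40 Gy. 30Gy-1 and 30Gy-2, and likewise 20Gy-3 and 30Gy-3 from different dose groups, were nearly identical. Over 6562 genes the log2 ratio of 20Gy-3 to 30Gy-3 had a spread of 0.111, and that of 30Gy-1 to 30Gy-2 a spread of 0.119, against 0.281 to 0.91 in the other 53 pairs. In the highest of 5 bins of expression level the spreads of these pairs were 0.032 and 0.058, against 0.228 to 1.199 in the others. Over all 6562 genes, 15 and 21 differed by more than 2-fold within these pairs. Without counts the sampling noise cannot be computed, but the spread of both pairs fell steadily with expression level and no value was identical. 30Gy-1 and 30Gy-2 were counted as 1 sample in means and SDs. Each count of changed genes is given below also with this pair averaged, with 20Gy-3 and 30Gy-3 left out, and with both, settings chosen after the data had been seen. 40Gy-1 lay nearest to 20Gy-2, with a spread of 0.519, and apart from 40Gy-2 and 40Gy-3, which lay 0.31 from each other.

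**Figure D1:**
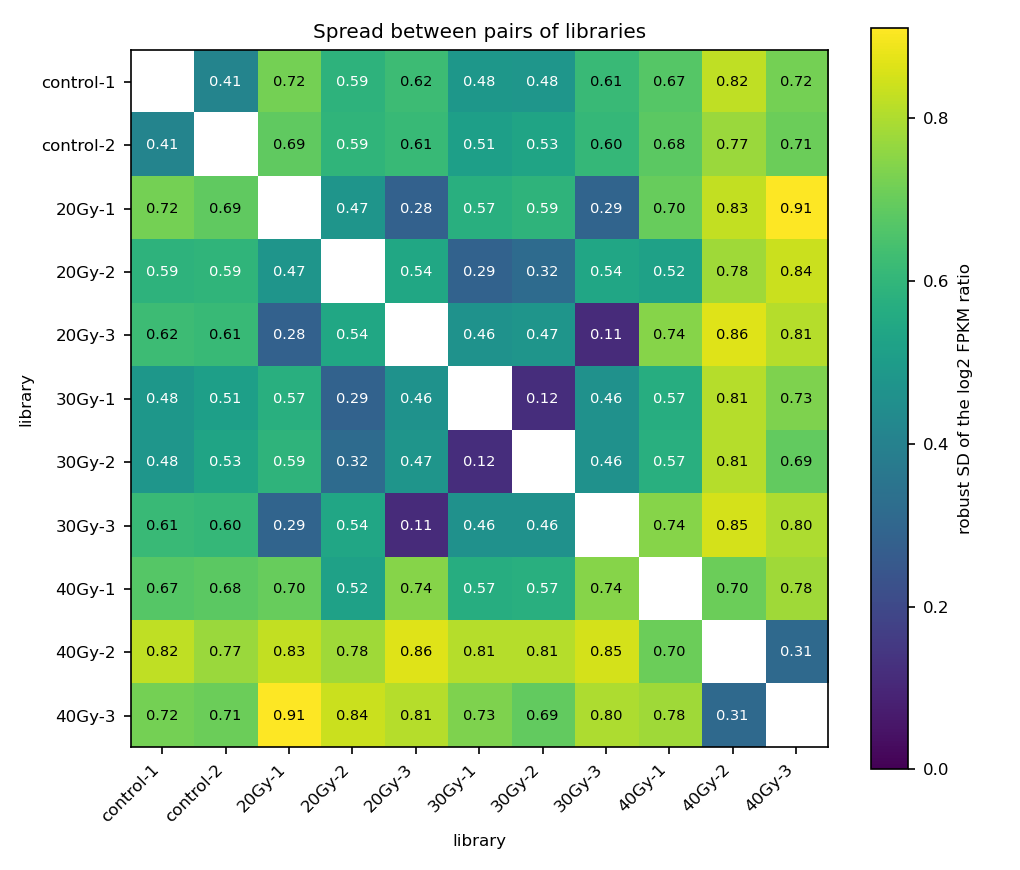
Robust SD of the log2 FPKM ratio between each pair of the 11 libraries, over genes with a mean of at least 5 FPKM, with libraries on both axes. The pairs 20Gy-3 with 30Gy-3 (0.111) and 30Gy-1 with 30Gy-2 (0.119) stand apart from the other 53 pairs (0.281 to 0.91).

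**Figure D2:**
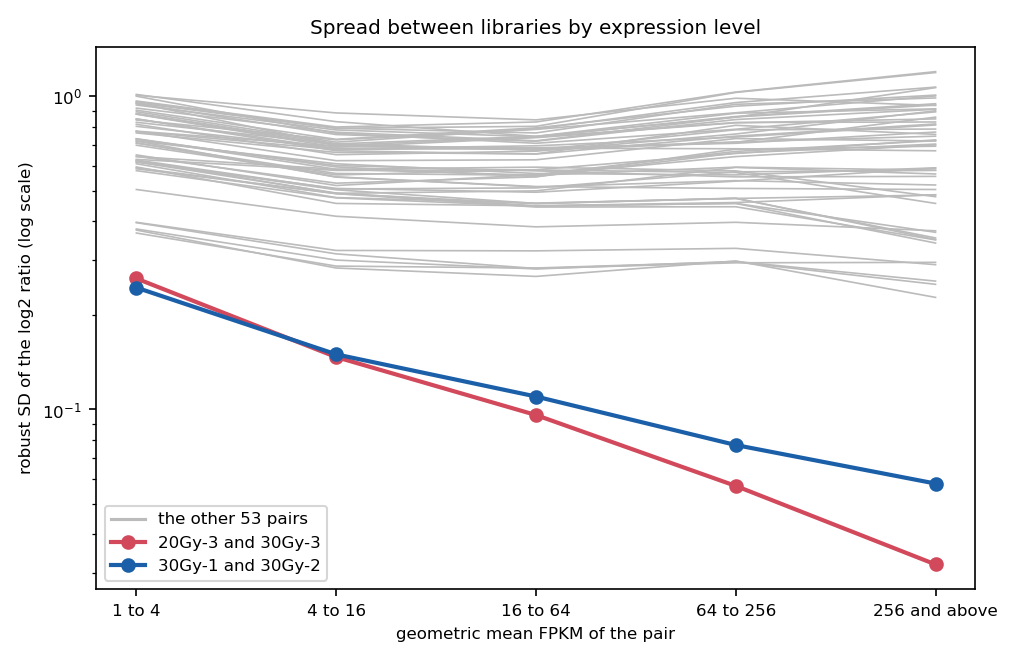
Robust SD of the log2 ratio (log scale) of each pair of libraries in 5 bins of the pair's geometric mean FPKM, with 1 line per pair. The near-identical pairs fall to 0.032 and 0.058 in the highest bin, while the other 53 pairs lie between 0.228 and 1.199 there.

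Averaged over the 3 doses, SCD and FASN of fatty acid synthesis rose far above control liver, and the apolipoprotein APOA4 fell far below it. SCD, the desaturase that makes monounsaturated fatty acids (ENSSSCG00000010554, chromosome 14, 111461560 to 111478033), rose from 5.05 ± 1.81 FPKM to 197 ± 62.2, 234 ± 92.0 and 45.6 ± 10.3 at 20, 30 and 40 Gy, a log2 change of 4.46 (SE 0.299, adjusted p = 6.75e-05). Fatty acid synthase, FASN (ENSSSCG00000029944, chromosome 12, 922405 to 937560), rose from 20.95 ± 1.78 to 797 ± 111, 629 ± 111 and 92.4 ± 22.8, by 4 on the log2 scale (SE 0.212, adjusted p = 1.07e-05). ACSL4, which activates polyunsaturated fatty acids for membrane lipids and is a ferroptosis driver (ENSSSCG00000012583, chromosome X, 89760863 to 89838103), rose from 2.82 ± 0.625 to 33.8 ± 9.59, 39.4 ± 11.5 and 18.1 ± 9.13 (log2 change 2.96, SE 0.313, adjusted p = 0.00113). Cyclin D1, CCND1, rose as well (2.34, SE 0.289, adjusted p = 0.00249). The lactoperoxidase LPO (2.33, SE 0.218, adjusted p = 6.42e-04), CYP26A1, which breaks down retinoic acid (2.30, SE 0.352, adjusted p = 0.00594), the glycolysis regulator PFKFB3 (2.17, SE 0.301, adjusted p = 0.0039), the tubulin-binding stathmin STMN1 (2.04, SE 0.296, adjusted p = 0.00465) and the macrophage scavenger receptor MARCO (2.70, SE 0.649, adjusted p = 0.0438) rose too.

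APOA4 (ENSSSCG00000040689, chromosome 9, 44201587 to 44204072) fell from 3395 ± 1233 FPKM to 13.8 ± 4.99, 13.4 ± 5.53 and 38.6 ± 6.64, a log2 change of -7.42 (SE 0.314, adjusted p = 1.75e-06). ACAA2, the thiolase of the last step of mitochondrial fatty acid oxidation (ENSSSCG00000004510, chromosome 1, 99284467 to 99310759), fell from 225 ± 108 to 4.63 ± 2.52, 5.66 ± 2.88 and 33.6 ± 37.3 (-4.47, SE 0.628, adjusted p = 0.00409). The lipid droplet coat protein PLIN2 fell from 43.9 ± 32.1 to 1.83 ± 0.833, 2.13 ± 1.41 and 13.3 ± 3.13 (-2.95, SE 0.4, adjusted p = 0.00353). The phosphomannomutase PMM1 (-3.82, SE 0.338), BUD13 (-3.48, SE 0.399), the mitochondrial carrier SLC25A34 (-3.31, SE 0.409) and the sulfotransferase SULT1B1 (-2.71, SE 0.244) fell too, with adjusted p of 4.54e-04, 0.0018, 0.00249 and 4.85e-04. The other large falls were in genes that overlap a neighbour: ZPR1, which overlaps APOA5 (-3.24, SE 0.428, adjusted p = 0.00317), MPST, which overlaps TST (-3.33, SE 0.387, adjusted p = 0.00185), and ACKR2, which overlaps ZNF662 (-3.01, SE 0.194, adjusted p = 5.83e-05). Calls were lost with single libraries left out for MARCO, with adjusted p of 0.413, 0.0728, 0.0653, 0.0716, 0.0816, 0.0813, 0.0508 and 0.0559 without control-2, 20Gy-1, 20Gy-2, 20Gy-3, 30Gy-1, 30Gy-2, 30Gy-3 and 40Gy-3 (0.0118 to 0.413 over its alternatives). Without control-1 they were lost for CYP26A1 (0.056), PFKFB3 (0.0519), STMN1 (0.0686) and ACAA2 (0.0696), and without control-2 for CYP26A1 (0.0997), PFKFB3 (0.0638), STMN1 (0.0638), SLC25A34 (0.0569), ZPR1 (0.0638) and PLIN2 (0.059), where the adjusted p ranged from 2.28e-05 to 0.0997 over all alternatives of these 7 genes. With the 30 Gy pair averaged and 20Gy-3 and 30Gy-3 left out, calls were lost for MARCO (0.193), CYP26A1 (0.0717), PFKFB3 (0.076), STMN1 (0.0805), ACAA2 (0.0723), ZPR1 (0.0719) and PLIN2 (0.0648).

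**Figure D3:**
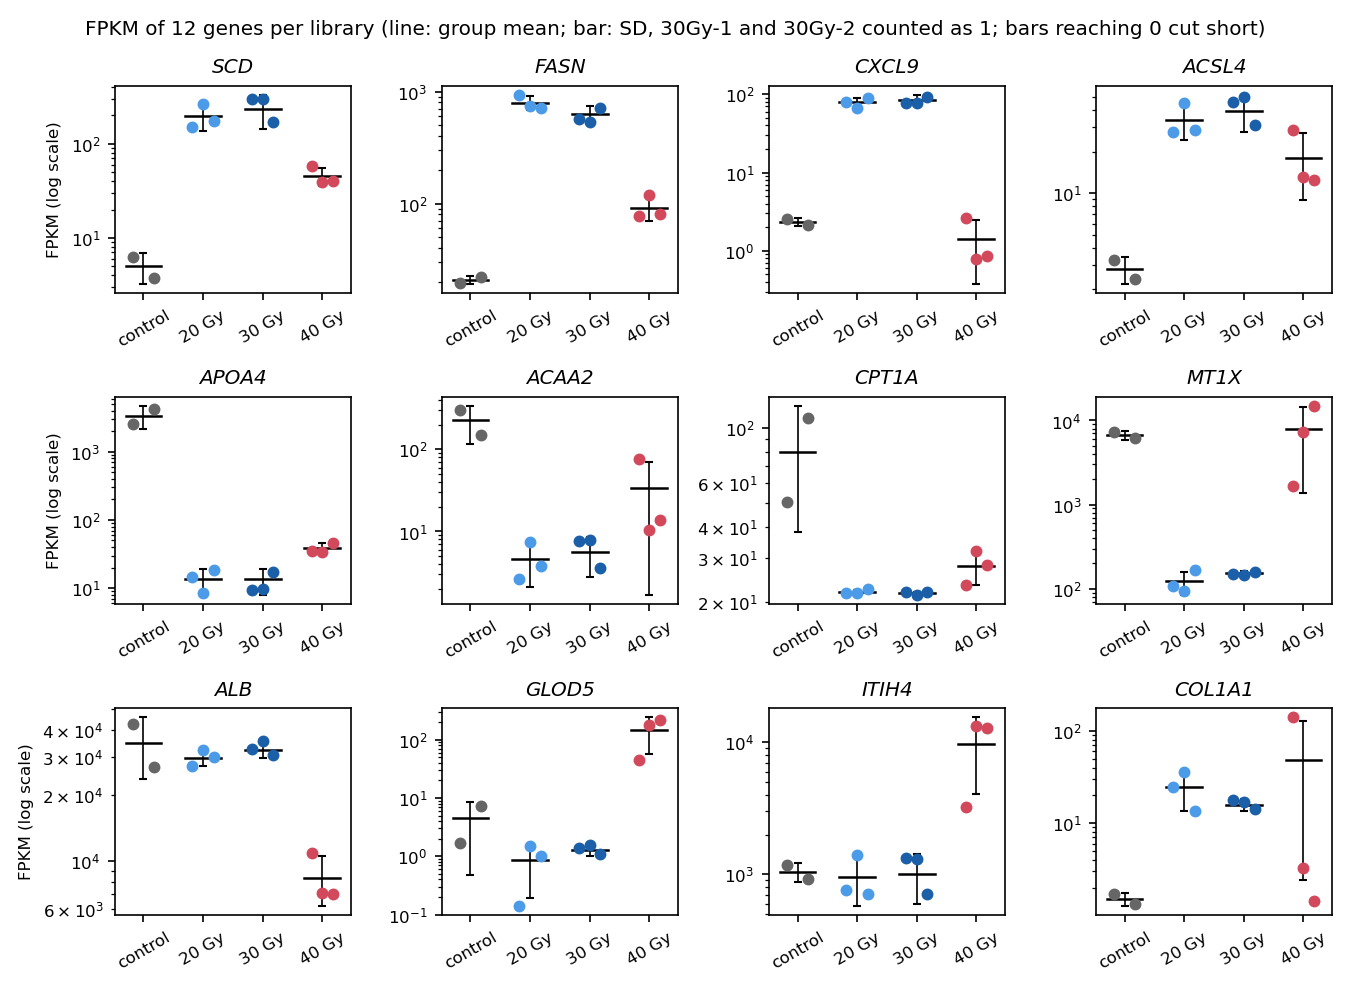
FPKM (log scale) of 12 genes in each library of the control, 20, 30 and 40 Gy groups, with points for libraries, a line at the group mean and a bar for the SD, where 30Gy-1 and 30Gy-2 count as 1. SCD, FASN and ACSL4 lie above control in every irradiated library, and COL1A1 at 40 Gy is 139.3 FPKM in 40Gy-1 against 3.242 and 1.449 in the others.

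In all, 548 of 11644 genes changed in irradiated against control liver (217 rose, 331 fell). Fatty acid oxidation genes fell as a group: 7 of 20 measured members fell (11 adjusted over the list alone), with a median log2 change of -0.66 (adjusted p = 2.03e-07, and adjusted p = 0.0159 with an estimated correlation, range 1.34e-08 to 0.0159). Besides ACAA2 these included ACADVL, the very long-chain acyl-CoA dehydrogenase, which overlaps DVL2 (-2.08, SE 0.227, adjusted p = 0.00137). Lipogenesis genes rose in 9 and fell in 1 of 16 (9 and 1 over the list alone), with a median of 1.02. As a list they had adjusted p = 2.7e-05, and adjusted p = 0.265 with an estimated correlation (range 3.03e-06 to 0.265). Cell cycle genes rose in 3 of 16 (13 up and 1 down over the list alone), with a median of 0.94. The list as a whole had adjusted p = 2.03e-07, and adjusted p = 0.265 with an estimated correlation (range 1.62e-10 to 0.265). Among them was cyclin B1, CCNB1 (1.09, SE 0.125, adjusted p = 0.0018). Its adjusted p was 0.0648 with the pair averaged and both others left out (range 3.78e-04 to 0.0648). NRF2 targets, genes of the oxidative stress response, rose in 6 of 17 (8 over the list alone), with a median of 0.43. Tested together, they had adjusted p = 0.00354, and adjusted p = 0.148 with an estimated correlation (range 3.25e-04 to 0.148).

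Extracellular matrix genes had 1 riser of 26 (3 over the list alone; median 0.79, adjusted p = 8.5e-06, and adjusted p = 0.848 with an estimated correlation, range 3.13e-07 to 0.848), the matricellular CCN2 (1.02, SE 0.209, adjusted p = 0.0238). That call was lost without control-1 (0.182), control-2 (0.17) and 20Gy-1 (0.0506) (range 0.00531 to 0.182). Immediate early genes had 1 riser of 17 (1 over the list alone), with a median of 0.92. Camera gave this list adjusted p = 1.8e-04, and adjusted p = 0.834 with an estimated correlation (range 3.13e-06 to 0.834). Interferon response genes had 1 of 23 (1 over the list alone), with a median of 0.69. Taken as 1 list, they had adjusted p = 2.56e-04, and adjusted p = 0.863 with an estimated correlation (range 1.38e-05 to 0.863). Cholesterol synthesis genes (0 of 20 by either adjustment, median 0.62, adjusted p = 0.011) and T and NK cell markers (0 of 15, median 0.26, adjusted p = 0.0364) were called upward, and secreted plasma proteins downward (2 of 20 fell, 3 over the list alone, median -0.18, adjusted p = 0.0121). Each had an adjusted p of 0.848 to 0.863 with an estimated correlation. Without control-2 the calls of cholesterol synthesis (0.305) and of T and NK cells (0.195) were lost, without 30Gy-3 that of T and NK cells (0.0534), and without control-1 (0.7) or with quantile normalization (0.856) that of plasma proteins. Over alternatives the ranges of these 3 lists were 2.38e-04 to 0.863, 0.00751 to 0.863 and 1.16e-05 to 0.856. The count of 548 genes was 320, 321, 327, 160 and 80 without 20Gy-1, 30Gy-1, 30Gy-2, control-1 and control-2, and 1416 without 40Gy-1. It was 337 with the 30 Gy pair averaged, 290 without 20Gy-3 and 30Gy-3, and 42 with both.

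**Figure D4:**
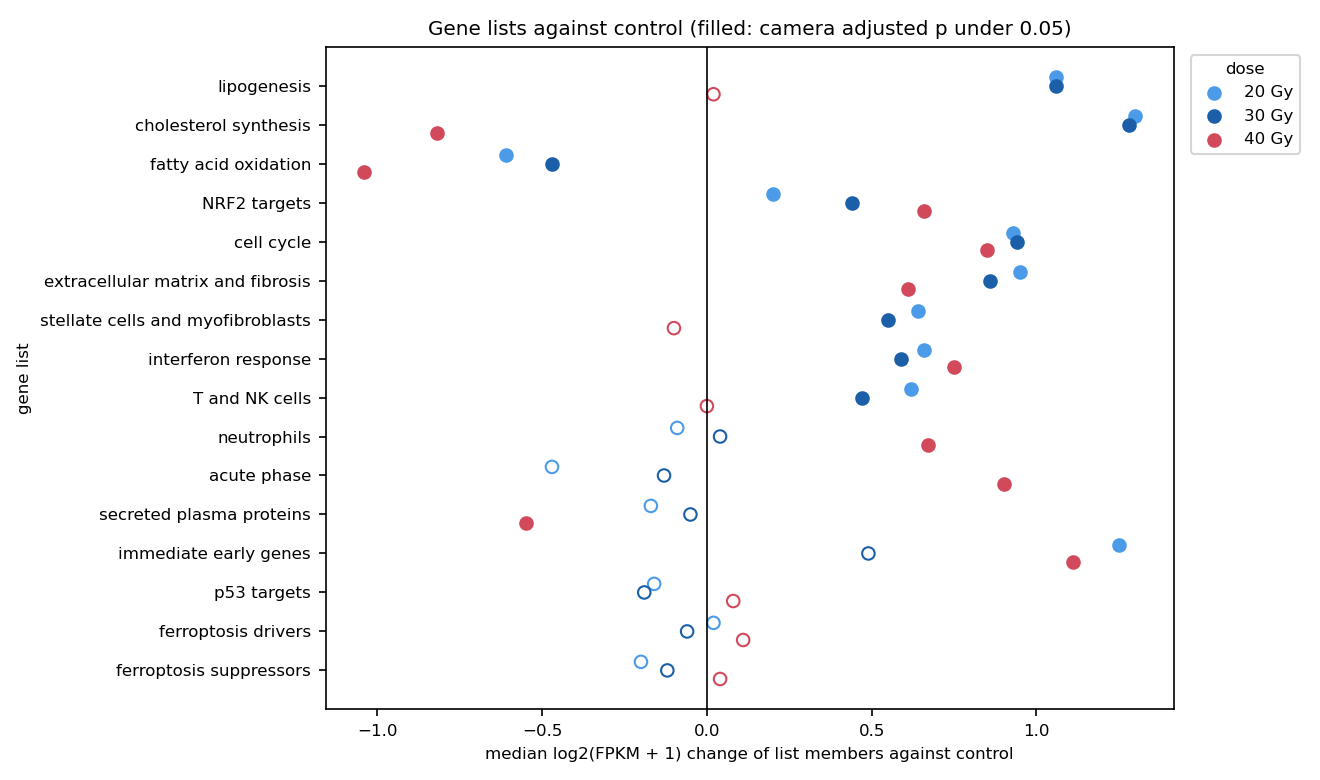
Median log2(FPKM + 1) change against control of the measured members of 16 gene lists at 20, 30 and 40 Gy, with filled points where the camera adjusted p was under 0.05. Lipogenesis and cholesterol synthesis lie above 1 at 20 and 30 Gy and at 0.02 and -0.82 at 40 Gy, and fatty acid oxidation lies below 0 at every dose.

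At 20 Gy FASN, SCD and CXCL9 rose, and APOA4, MT1X and ACAA2 fell. FASN was 36.2-fold and SCD 32.5-fold higher than in control on the FPKM + 1 scale (log2 5.18, SE 0.247, adjusted p = 3.89e-06, and 5.02, SE 0.349, adjusted p = 9.58e-05). PNPLA3, a lipase and acyltransferase of lipid droplets (ENSSSCG00000027266, chromosome 5, 5075608 to 5092599), rose from 0.566 ± 0.223 to 30.3 ± 20.8 FPKM (4.13, SE 0.519, adjusted p = 0.00241). The interferon-induced chemokine CXCL9 (ENSSSCG00000032777, chromosome 8, 71665541 to 71670236) rose from 2.34 ± 0.264 to 79.0 ± 11.5 (4.57, SE 0.292, adjusted p = 5.18e-05). The metal-binding metallothionein MT1X (ENSSSCG00000030300) fell from 6698 ± 808 to 122 ± 37.9 (-5.80, SE 0.694, adjusted p = 0.00186). APOA4 fell by 7.85 on the log2 scale (SE 0.367, adjusted p = 3.89e-06), ACAA2 by 5.33 (SE 0.733, adjusted p = 0.00372), the sulfotransferase SULT1A3, which overlaps BOLA2B, by 4.13 (SE 0.535, adjusted p = 0.00274) and PMM1 by 4.12 (SE 0.395, adjusted p = 6.52e-04). With the 30 Gy pair averaged and 20Gy-3 and 30Gy-3 left out, the call of ACAA2 was lost (0.0683, range 1.64e-05 to 0.0683).

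Of 11644 genes, 492 changed at 20 Gy (236 rose, the others fell). Lipogenesis genes rose in 8 of 16 (10 up and 1 down over the list alone), with a median of 1.06. In the test of the list they had adjusted p = 1.19e-07, and adjusted p = 0.135 with an estimated correlation (range 5.63e-09 to 0.135). Among them was the acetyl-CoA synthetase ACSS2 (2.59, SE 0.326, adjusted p = 0.00241). Fatty acid oxidation genes fell in 6 of 20 (9 down and 1 up over the list alone), with a median of -0.61. As a list they had adjusted p = 2.38e-04, and adjusted p = 0.105 with an estimated correlation (range 1.85e-05 to 0.105). ACADVL fell from 178 ± 44.2 to 36.9 ± 9.85 FPKM (-2.24, SE 0.265, adjusted p = 0.00172). CPT1A, which lets fatty acids into mitochondria, fell by 1.71 on the log2 scale (SE 0.281, adjusted p = 0.00885), with an adjusted p of 0.0517 without control-2 (range 7.99e-04 to 0.126). Cholesterol synthesis genes had 1 riser of 20 (8 over the list alone), with a median of 1.3. The list as a whole had adjusted p = 5.93e-07, and adjusted p = 0.751 with an estimated correlation (range 7.88e-11 to 0.751). Cell cycle genes had 3 of 16 (11 up and 1 down over the list alone), with a median of 0.93. Tested together, they had adjusted p = 1.56e-06, and adjusted p = 0.368 with an estimated correlation (range 7.38e-09 to 0.368). Among them was CCNB1 (1.03, SE 0.146, adjusted p = 0.0042). With the pair averaged and both others left out, the calls of CCNB1 (0.0972, range 7.12e-04 to 0.0972) and ACSS2 (0.0567, 7.36e-05 to 0.0567) were lost.

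Other lists were called at 20 Gy with few or no single members past the threshold. Extracellular matrix genes had 1 of 26 (1 over the list alone, median 0.95, adjusted p = 6.78e-05), immediate early genes 0 of 17 (1, median 1.25, adjusted p = 1.45e-04), interferon response genes 0 of 23 (2, median 0.66, adjusted p = 0.00179), T and NK cell markers 0 of 15 (4, median 0.62, adjusted p = 0.00294) and stellate cell markers 1 of 16 (2, median 0.64, adjusted p = 0.00913). Complement genes were called downward with 1 of 18 (2 over the list alone, median -0.19, adjusted p = 0.0414). For all 6 the estimated correlation gave an adjusted p of 0.751, and the lowest adjusted p over alternatives was 1.82e-09, 8.77e-07, 2.19e-05, 2.83e-04, 6e-04 and 2.35e-04 in the same order. NRF2 targets rose in 3 of 17 (6 over the list alone), with a median of 0.2. Camera gave this list adjusted p = 0.0497, and adjusted p = 0.368 with an estimated correlation (range 0.00982 to 0.368). Among them was UGDH, of glucuronide synthesis (1.67, SE 0.26, adjusted p = 0.00653), with an adjusted p of 0.0664 without control-2 (range 4.96e-04 to 0.111). The NRF2 call was lost without control-1, 20Gy-1, 20Gy-2, 30Gy-2, 30Gy-3, 40Gy-1, 40Gy-2 and 40Gy-3 (0.056, 0.0583, 0.107, 0.0512, 0.066, 0.0771, 0.0516 and 0.122), that of complement without control-1, 20Gy-1 and 20Gy-3 and with quantile normalization (0.677, 0.0619, 0.0728 and 0.295), that of stellate cells without control-1 and 20Gy-2 (0.206 and 0.0515) and that of interferon without control-2 (0.0523). The count of 492 genes was 167, 258, 287, 295, 228 and 118 without 20Gy-1, 20Gy-3, 30Gy-1, 30Gy-2, control-1 and control-2, and 1644 without 40Gy-1. It was 295 with the 30 Gy pair averaged, 206 without 20Gy-3 and 30Gy-3, and 59 with both.

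At 30 Gy the leading genes were those of 20 Gy. SCD was 42.0-fold and FASN 27.3-fold higher than in control (log2 5.39, SE 0.349, adjusted p = 4.76e-05, and 4.77, SE 0.247, adjusted p = 8.78e-06). CXCL9 rose to 85.5 ± 11.4 FPKM (4.65, SE 0.292, adjusted p = 4.44e-05) and PNPLA3 to 28.6 ± 18.5 (4.32, SE 0.519, adjusted p = 0.00227). APOA4 fell by 8.02 on the log2 scale (SE 0.367, adjusted p = 3.82e-06) and MT1X by 5.44 (SE 0.694, adjusted p = 0.00301), to 155 ± 7.33 FPKM. ACAA2 fell by 4.92 (SE 0.733, adjusted p = 0.00649), PMM1 by 4.01 (SE 0.395, adjusted p = 8.53e-04) and SULT1A3 by 3.89 (SE 0.535, adjusted p = 0.00459). The call of ACAA2 was lost without control-1 (0.0623, range 5.07e-05 to 0.384) and that of SULT1A3 without control-2 (0.0642, range 2.69e-04 to 0.264). With the 30 Gy pair averaged and 20Gy-3 and 30Gy-3 left out, 30 Gy is left with 1 library. Calls were then lost for MT1X (0.258, range 1.43e-05 to 0.258), PMM1 (0.133, 2.01e-05 to 0.133), ACAA2 (0.384) and SULT1A3 (0.264).

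Of 11644 genes, 353 changed at 30 Gy (154 rose, 199 fell). Lipogenesis genes rose in 6 and fell in 1 of 16 (10 and 1 over the list alone), with a median of 1.06. Taken as 1 list, they had adjusted p = 1.12e-08, and adjusted p = 0.0995 with an estimated correlation (range 8.59e-10 to 0.0995). Fatty acid oxidation genes fell in 4 of 20 (9 over the list alone), with a median of -0.47. In the test of the list they had adjusted p = 2.57e-04, and adjusted p = 0.0995 with an estimated correlation (range 1.22e-05 to 0.0995). Among them was ACADVL (-2.10, SE 0.265, adjusted p = 0.00285), at 0.271 with the pair averaged and both others left out (range 1.67e-04 to 0.271). NRF2 targets rose in 4 of 17 (6 over the list alone), with a median of 0.44. As a list they had adjusted p = 0.0093, and adjusted p = 0.156 with an estimated correlation (range 0.0033 to 0.156). Among them was UGDH (1.76, SE 0.26, adjusted p = 0.00638, 0.07 without control-2, range 4.89e-04 to 0.377). Cholesterol synthesis genes had 1 riser of 20 (9 over the list alone), with a median of 1.28. The list as a whole had adjusted p = 5.64e-07, and adjusted p = 0.736 with an estimated correlation (range 1.07e-10 to 0.736). Cell cycle genes had 2 of 16 (10 up and 1 down over the list alone), with a median of 0.94. Tested together, they had adjusted p = 3.59e-07, and adjusted p = 0.292 with an estimated correlation (range 3.11e-10 to 0.292). Among them was CCNB1 (0.94, SE 0.146, adjusted p = 0.00757), with 0.0528 without control-1 and 0.0692 without control-2 (range 0.00115 to 0.469).

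Extracellular matrix genes (0 of 26 by either adjustment, median 0.86, adjusted p = 3.81e-05), interferon response genes (0 of 23, 1 over the list alone, median 0.59, adjusted p = 5.74e-04), T and NK cell markers (0 of 15, 4 over the list alone, median 0.47, adjusted p = 0.00154) and stellate cell markers (0 of 16 by either adjustment, median 0.55, adjusted p = 0.0145) were called upward at 30 Gy as lists. With an estimated correlation the adjusted p was 0.895 for interferon response and 0.858 for the other 3, and the lowest values over alternatives were 1.07e-10, 8.75e-06, 1.29e-04 and 7.39e-04 in the same order. The stellate call was lost without control-1 (0.328). The count of 353 genes was 218, 134, 136, 191, 197 and 75 without 20Gy-1, 30Gy-1, 30Gy-2, 30Gy-3, control-1 and control-2, and 1110 without 40Gy-1. It was 130 with the 30 Gy pair averaged, 126 without 20Gy-3 and 30Gy-3, and 8 with both.

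At 40 Gy GLOD5, CYP26A1 and TNFRSF12A rose, while albumin, APOA4 and ACSL1 fell. GLOD5, a glyoxalase domain protein (ENSSSCG00000031477, chromosome X, 42877034 to 42889285), rose from 4.54 ± 4.05 to 149 ± 92.0 FPKM (log2 4.70, SE 0.658, adjusted p = 0.0038). CYP26A1 rose from 2.06 ± 0.477 to 56.2 ± 23.4 (4.13, SE 0.412, adjusted p = 0.00109). TNFRSF12A, the receptor of the cytokine TWEAK, rose from 0.908 ± 0.251 to 35.2 ± 18.7 (4.13, SE 0.713, adjusted p = 0.00891), the stress-induced IER3 from 2.5 ± 0.745 to 32.8 ± 0.323 (3.29, SE 0.822, adjusted p = 0.0403) and MARCO from 6.23 ± 7.72 to 43.8 ± 30.9 (3.03, SE 0.757, adjusted p = 0.0404). Albumin, ALB (ENSSSCG00000008948, chromosome 8, 69643427 to 69663152), fell from 34790 ± 10970 to 8326 ± 2152 (-2.06, SE 0.301, adjusted p = 0.0045). APOA4 fell by 6.39 on the log2 scale (SE 0.367, adjusted p = 3.68e-05), the cytochrome P450 CYP2A19 by 4.54 (SE 1.15, adjusted p = 0.0417), the acyl-CoA synthetase ACSL1 by 4.10 (SE 0.699, adjusted p = 0.00874), SLC25A34 by 3.75 (SE 0.478, adjusted p = 0.00254) and the hemoglobin gene HBB by 3.73 (SE 0.975, adjusted p = 0.046).

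Of 11644 genes, 861 changed at 40 Gy (348 rose, 513 fell). Fatty acid oxidation genes fell in 8 of 20 (14 over the list alone; median -1.04, adjusted p = 2.15e-09, and adjusted p = 0.00686 with an estimated correlation, the highest value over 25 alternatives). The carnitine carrier SLC25A20 fell from 72.8 ± 10.9 to 13.5 ± 8.24 FPKM (-2.48, SE 0.361, adjusted p = 0.00432) and ACADVL by 1.89 on the log2 scale (SE 0.265, adjusted p = 0.0038). Secreted plasma proteins fell in 4 of 20 (6 over the list alone), with a median of -0.55. Camera gave this list adjusted p = 1.03e-04, and adjusted p = 0.541 with an estimated correlation (range 8.71e-08 to 0.541). NRF2 targets rose in 4 of 17 (7 up and 1 down over the list alone), with a median of 0.66. Taken as 1 list, they had adjusted p = 0.00427, and adjusted p = 0.15 with an estimated correlation (range 3.58e-04 to 0.15). Among them SRXN1, which repairs oxidized peroxiredoxins, rose from 1.93 ± 0.746 to 23.6 ± 8.53 (3.02, SE 0.357, adjusted p = 0.00206). Cell cycle genes rose in 4 of 16 (4 over the list alone; median 0.85, adjusted p = 1.24e-04, and adjusted p = 0.541 with an estimated correlation, range 8.49e-07 to 0.541), CCNB1 by 1.31 on the log2 scale (SE 0.146, adjusted p = 0.00152). Immediate early genes rose in 2 of 17 (4 over the list alone), with a median of 1.11. In the test of the list they had adjusted p = 3.76e-04, and adjusted p = 0.741 with an estimated correlation (range 3.4e-08 to 0.741).

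Neutrophil markers rose in 3 of 9 (4 over the list alone), with a median of 0.67. As a list they had adjusted p = 0.0172, and adjusted p = 0.267 with an estimated correlation (range 0.00392 to 0.267). Among them was the receptor of granulocyte colony-stimulating factor, CSF3R (1.07, SE 0.21, adjusted p = 0.0156). Acute phase genes had 1 riser of 11 (1 over the list alone; median 0.9, adjusted p = 0.031, and adjusted p = 0.885 with an estimated correlation, range 0.00102 to 0.885), ITIH4, which rose from 1042 ± 176 to 9762 ± 5671 (2.98, SE 0.592, adjusted p = 0.0163). Extracellular matrix genes rose in 2 of 26 (4 over the list alone; median 0.61, adjusted p = 0.00162, and adjusted p = 0.885 with an estimated correlation, range 6.4e-06 to 0.885), the gelatinase MMP2 (1.75, SE 0.291, adjusted p = 0.00787) and COL14A1 (1.31, SE 0.245, adjusted p = 0.0124). Interferon response genes had 1 riser of 23 (1 over the list alone), with a median of 0.75. The list as a whole had adjusted p = 0.00723, and adjusted p = 0.885 with an estimated correlation (range 1.48e-05 to 0.921). Cholesterol synthesis genes fell in 2 of 20 (2 over the list alone), with a median of -0.82. Tested together, they had adjusted p = 0.00845, and adjusted p = 0.885 with an estimated correlation (range 3.02e-07 to 0.885). Erythroid genes fell in 2 of 4 (2 over the list alone), with a median of -1.53. Camera gave this list adjusted p = 0.0105, and adjusted p = 0.728 with an estimated correlation (range 1.52e-04 to 0.728). The lipogenesis list was not called (5 rose and 2 fell, adjusted p = 0.755). Without 40Gy-1 the calls of matrix (0.839), interferon (0.921) and neutrophil genes (0.0584) were lost, without control-2 those of interferon (0.135) and acute phase (0.198), without control-1 (0.336) or with quantile normalization (0.0783) that of cholesterol synthesis, without 40Gy-2 those of cholesterol synthesis (0.0726) and acute phase (0.0726) and without 40Gy-3 the same (0.109 and 0.167).

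Some 40 Gy calls were lost without single libraries of any group. IER3 was lost without control-1, control-2, 20Gy-1, 20Gy-3, 30Gy-2, 40Gy-2 and 40Gy-3 (0.207, 0.138, 0.0518, 0.0534, 0.0549, 0.107 and 0.0808, range 0.00333 to 0.207). MARCO was lost without control-2, 20Gy-1, 20Gy-2, 20Gy-3, 30Gy-1, 30Gy-2, 40Gy-2 and 40Gy-3 (0.252, 0.0629, 0.0501, 0.0612, 0.0639, 0.0631, 0.0629 and 0.0706, range 0.0128 to 0.252). CYP2A19 was lost without control-1, control-2, 20Gy-1, 20Gy-3, 30Gy-1, 30Gy-2, 40Gy-2 and 40Gy-3 (0.196, 0.162, 0.052, 0.0541, 0.0557, 0.0552, 0.11 and 0.0858, range 0.00335 to 0.196). HBB was lost without control-1, 20Gy-1, 20Gy-3, 30Gy-1, 30Gy-2, 40Gy-2 and 40Gy-3 (0.314, 0.0622, 0.0696, 0.0701, 0.0689, 0.145 and 0.106, range 0.00242 to 0.314). Without control-1 the adjusted p was 0.0781 for TNFRSF12A, 0.0613 for ACSL1, 0.0873 for ITIH4, 0.0536 for MMP2 and 0.0736 for COL14A1. Without control-2 it was 0.0554, 0.0656, 0.103, 0.0612 and 0.0847 for the same genes and 0.12 for CSF3R, and without 40Gy-2 0.0593 for ITIH4 and 0.0543 for CSF3R (ranges 0.00175 to 0.0781, 2.82e-05 to 0.131, 8.12e-05 to 0.158, 0.00217 to 0.11, 1.44e-04 to 0.156 and 0.00486 to 0.14). The count of 861 genes was 545, 526, 354, 224 and 274 without 30Gy-1, 30Gy-2, 40Gy-2, control-1 and control-2, and 2655 without 40Gy-1. It was 548 with the 30 Gy pair averaged, 551 without 20Gy-3 and 30Gy-3, and 123 with both. With only the 5 libraries compared, so that the spread of the others does not enter, 31 genes were called. GLOD5 (0.108), MARCO (0.225), ALB (0.197), ACSL1 (0.131), SLC25A34 (0.0599) and HBB (0.192) were then lost, where the ranges not yet given were 7.23e-05 to 0.108 for GLOD5, 1.19e-04 to 0.197 for ALB and 9.02e-05 to 0.0599 for SLC25A34. The same fit lost ACADVL (0.0696, 2.4e-04 to 0.0696), SLC25A20 (0.114, 3.65e-05 to 0.114), SRXN1 (0.0696, 7.23e-05 to 0.0696), CCNB1 (0.0696, 3.9e-04 to 0.0696) and, within the ranges above, ITIH4, MMP2, COL14A1 and CSF3R.

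Among the genes of ferroptosis and of the p53 response, ACSL4 rose at every dose against control, where most others did not pass. ACSL4 rose by 3.16 on the log2 scale at 20 Gy (SE 0.365, adjusted p = 0.00159), 3.48 at 30 Gy (adjusted p = 0.00116, 0.114 with the pair averaged and both others left out, range 4.91e-06 to 0.114) and 2.23 at 40 Gy (adjusted p = 0.00723), the last with an adjusted p of 0.0629 without control-2 (range 3.69e-04 to 0.111). Of 19 measured ferroptosis drivers, 2, 1 and 1 rose at 20, 30 and 40 Gy and 0 fell (2, 3 and 2 rose over the list alone), and camera gave adjusted p of 0.832, 0.653 and 0.585 for the list. The other driver called at 20 Gy was CHAC1, which breaks down glutathione (2.83, SE 0.565, adjusted p = 0.0222). Its call was lost without control-1, control-2, 20Gy-1 and 20Gy-3 (0.117, 0.138, 0.093 and 0.0728, range 3.7e-04 to 0.138). Of 20 measured suppressors, 1, 1 and 2 rose and 0, 0 and 1 fell (1, 1 and 3 rose and 0, 0 and 3 fell over the list alone), with adjusted p of 0.98, 0.765 and 0.924. The riser at every dose was SCD. At 40 Gy the peroxidase PRDX6 fell from 249 ± 16.8 to 87.5 ± 8.78 FPKM (-1.50, SE 0.193, adjusted p = 0.00254, 0.0904 with only the groups compared, range 2.46e-04 to 0.0904), and the glutathione synthesis subunit GCLM rose (1.16, SE 0.282, adjusted p = 0.0371). GCLM was lost without control-1, control-2, 20Gy-1, 20Gy-3, 30Gy-1, 30Gy-2, 30Gy-3, 40Gy-2 and 40Gy-3 (0.164, 0.155, 0.0613, 0.0562, 0.0633, 0.0643, 0.0502, 0.12 and 0.0874, range 2.38e-04 to 0.236). With an estimated correlation the adjusted p of the 2 ferroptosis lists lay between 0.856 and 0.987 at all doses. At 20 Gy the suppressors had a median of -0.2 and a mean of 0.23, and camera pointed upward.

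GPX4, the peroxidase that clears lipid hydroperoxides, was at 90.7 ± 7.28 FPKM in control and 59.6 ± 11.9, 75.3 ± 12.1 and 60.8 ± 17.9 at 20, 30 and 40 Gy, and did not pass the test in irradiated against control liver (-0.48, SE 0.227, adjusted p = 0.271). The transferrin receptor TFRC (0.22, SE 0.327, adjusted p = 0.755), the ferritin light chain FTL (-0.62, SE 0.263, adjusted p = 0.221), the heme oxygenase HMOX1 (-0.54, SE 0.253, adjusted p = 0.265) and the prostaglandin synthase PTGS2, which overlaps PLA2G4A (0.56, SE 0.494, adjusted p = 0.575), did not pass it either. The same held for the p53 targets CDKN1A (-0.23, SE 0.273, adjusted p = 0.684) and MDM2 (0.02, SE 0.14, adjusted p = 0.965). Of 21 measured p53 targets, 1 fell at 20 Gy (2 over the list alone) and 0 changed at 30 or 40 Gy by either adjustment, with camera adjusted p of 0.554, 0.653 and 0.98. The rotation test fry put the list lower at 20 and 30 Gy (adjusted p = 0.0184 and 0.0273), and at 40 Gy the median was 0.08 while camera pointed downward. The faller was cyclin G1, CCNG1 (-1.17, SE 0.279, adjusted p = 0.0455). Its call was lost without control-1, control-2, 20Gy-1, 20Gy-3, 30Gy-1, 30Gy-2, 40Gy-2 and 40Gy-3 (0.246, 0.123, 0.173, 0.117, 0.073, 0.0612, 0.065 and 0.0591, range 0.00254 to 0.246). ALB (-0.76, SE 0.258, adjusted p = 0.131) and the collagen gene COL1A1 (2.74, SE 1.13, adjusted p = 0.209) passed in irradiated against control liver only without 40Gy-1 (0.016 and 0.00305) or with sample quality weights (0.0226 and 0.024). Their ranges over alternatives were 0.016 to 0.638 and 0.00305 to 0.532.

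More of these genes differed between the doses, although camera called none of the 3 lists (adjusted p of 0.526 to 0.882). Against 20 and 30 Gy, 2 and 1 drivers rose and 2 and 2 fell at 40 Gy, 2 and 1 suppressors rose and 2 and 3 fell, and 1 and 1 p53 targets rose and 1 and 2 fell. PRDX6 (-0.90 and -1.10, adjusted p = 0.00975 and 0.00417), SCD (-2.07 and -2.44, adjusted p = 0.00327 and 0.0016) and the p53 target DDB2 (-1.46 and -1.31, adjusted p = 0.00316 and 0.00554) fell against both, with adjusted p up to 0.155 and 0.359 for PRDX6 and 0.0677 and 0.361 for DDB2 over alternatives. NCOA4, which delivers ferritin for breakdown, rose (1.07 and 0.74, adjusted p = 0.00374 and 0.0206). CHAC1 fell against 20 Gy (-2.47, adjusted p = 0.0128), a call lost without 20Gy-1 (0.0608) and 20Gy-3 (0.0561; range 3.68e-05 to 0.0827). Calls lost without 40Gy-2, and without others, were TFRC (0.132), SLC39A14 (0.113), TXNRD1 (0.0948), NQO1 (0.141) and TIGAR (0.0768) against 20 Gy, and CHAC1 (0.101), ACSL4 (0.141), NCOA4 (0.0847), TXNRD1 (0.158), AIFM2 (0.132), PLK3 (0.0914) and FDXR (0.182) against 30 Gy. Over alternatives these lay between 6.67e-06 and 0.236, and between 7.04e-06 and 0.564. Fry put the p53 list higher at 40 Gy in both (adjusted p = 0.00181 and 0.00519).

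At no dose against control did camera call the other lists (adjusted p 0.0511 to 0.974). They were iron handling, the unfolded protein and integrated stress responses, hypoxia, senescence, coagulation, cytochromes P450, bile acids and the urea cycle. Others were gluconeogenesis, pericentral and periportal hepatocytes, antigen presentation, fetal liver and the circadian clock. Cell types were sinusoidal and vascular endothelium, macrophages, B and plasma cells and bile duct cells. Fry called B and plasma cells upward at 40 Gy (adjusted p = 0.0213). Of the lists camera called, it called 4 of 11, 4 of 9 and 5 of 11 at 20, 30 and 40 Gy.

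Calls overlapped between the doses. Of the genes called at 20 and at 30 Gy, 133 rose and 168 fell in both, where independent lists would share 3.12 and 4.38. At 20 and 40 Gy 64 rose and 124 fell in both (7.05 and 11.3 for independent lists), and at 30 and 40 Gy 41 rose and 106 fell in both (4.6 and 8.77). Unchanged groups simulated against the same controls shared 0 genes in each of 50 simulations, which leave out the effects and so do not measure what the shared controls add. At all 3 doses, 40 genes rose and 97 fell, 137 in all. The controls cannot be split into groups of at least 2, so part of the excess may come from the shared controls, and 20Gy-3 and 30Gy-3 being nearly identical adds to the overlap of 20 and 30 Gy. The 137 genes were 67, 80, 60, 61, 83, 84, 61 and 27 without 20Gy-1, 20Gy-3, 30Gy-1, 30Gy-2, 30Gy-3, 40Gy-2, control-1 and control-2, and 374 without 40Gy-1. They were 59 with the 30 Gy pair averaged, 53 without 20Gy-3 and 30Gy-3, 6 with both, and 7 with only the groups compared in each fit.

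Between 30 and 20 Gy no single gene passed the test: limma called 0 of 11644 genes, with 280 at an unadjusted p under 0.05. Lowest in unadjusted p were IQANK1, which overlaps SCRIB and FAM83H (log2 difference -0.82, SE 0.185), PAQR6 (0.61, SE 0.151), the transcriptional coactivator CITED1 (0.56, SE 0.142), CYB5RL (-0.78, SE 0.201) and MYPOP (-0.73, SE 0.191), each with a limma adjusted p of 1. Immediate early genes were lower at 30 Gy as a list (0 of 17 members by either adjustment, median -0.8, adjusted p = 1.13e-05, and adjusted p = 0.971 with an estimated correlation, range 1.61e-09 to 0.975). The count was 2 without 20Gy-2, 3 without 20Gy-3, 2 without 20Gy-3 and 30Gy-3, and 1 with the 30 Gy pair averaged as well. With sample quality weights, which gave 30Gy-2 a weight of 5.42 and 40Gy-1 one of 0.11, 5688 genes were called, among them these 5 (adjusted p of 0.00135 to 0.00436, range 0.00135 to 1).

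Between 40 Gy and the lower doses CXCL9, IDI1 and CBR2 fell, and SULT1A3, MT1X and GLOD5 rose. CXCL9 was at 79.0 ± 11.5 FPKM at 20 Gy, 85.5 ± 11.4 at 30 Gy and 1.41 ± 1.03 at 40 Gy, so that it fell by 5.12 on the log2 scale from 20 Gy (SE 0.261, adjusted p = 2.23e-05) and by 5.2 from 30 Gy (SE 0.261, adjusted p = 1.94e-05). IDI1, an isomerase of cholesterol synthesis, fell from 1541 ± 133 and 1835 ± 138 to 89.7 ± 107 (-4.78, SE 0.638, adjusted p = 0.00192, and -5.06, SE 0.638, adjusted p = 0.00155). The carbonyl reductase CBR2, which overlaps LOC102160997, fell from 3393 ± 1155 and 2146 ± 1007 to 33.9 ± 19.6 (-6.72, SE 0.644, adjusted p = 4.08e-04, and -5.87, SE 0.644, adjusted p = 7.75e-04). EXTL1, a glycosyltransferase, fell by 5.53 (SE 0.643, adjusted p = 9.32e-04) and 5.30 (SE 0.643, adjusted p = 0.00127), and THRSP, a regulator of lipogenesis, by 4.83 (SE 1.21, adjusted p = 0.026) and 5.45 (SE 1.21, adjusted p = 0.0188). SULT1A3 rose from 1.32 ± 0.931 and 1.477 ± 1.489 to 166 ± 76.2 (6.11, SE 0.478, adjusted p = 1.98e-04, and 5.88, SE 0.478, adjusted p = 2.55e-04), and MT1X from 122 ± 37.9 and 155 ± 7.33 to 7901 ± 6520 (5.56, SE 0.621, adjusted p = 7.38e-04, and 5.2, SE 0.621, adjusted p = 0.00117). GLOD5 rose by 6.12 (SE 0.589, adjusted p = 4.08e-04) and 5.73 (SE 0.589, adjusted p = 6.64e-04), and SCNN1B, a subunit of the epithelial sodium channel, by 4.03 (SE 0.469, adjusted p = 9.29e-04) and 4.12 (SE 0.469, adjusted p = 8.8e-04). The metallothionein MT3 is listed at 0 in every library of 20 and 30 Gy and at 0.834, 225 and 368 FPKM in 40Gy-1, 40Gy-2 and 40Gy-3.

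Of 11644 genes, 1748 differed between 40 and 20 Gy (945 higher and 803 lower at 40 Gy) and 1417 between 40 and 30 Gy (693 and 724). Median-of-ratios scaling turned the majority against 20 Gy (790 higher and 907 lower) and gave 617 and 817 against 30 Gy. Cholesterol synthesis genes fell in 12 of 20 against 20 Gy (19 over the list alone; median -2.09, adjusted p = 2.99e-11, and adjusted p = 0.602 with an estimated correlation, range 5.07e-14 to 0.602) and in 11 of 20 against 30 Gy (16), with a median of -2.07. Taken as 1 list, they had adjusted p = 1.54e-10, and adjusted p = 0.667 with an estimated correlation (range 1.26e-13 to 0.667). The mevalonate kinase MVK fell from 311 ± 45.6 and 293 ± 65.4 to 31.7 ± 31.3 FPKM (-3.66, SE 0.507, adjusted p = 0.00221, and -3.49, SE 0.507, adjusted p = 0.00282). Lipogenesis genes fell in 9 of 16 against 20 Gy (12 over the list alone; median -2.04, adjusted p = 3.75e-08, and adjusted p = 0.254 with an estimated correlation, range 1.07e-09 to 0.254) and in 10 of 16 against 30 Gy (12), with a median of -1.82. In the test of the list they had adjusted p = 8.13e-08, and adjusted p = 0.283 with an estimated correlation (range 4.17e-09 to 0.283). PNPLA3 fell by 4.11 (SE 0.464, adjusted p = 8.03e-04) and by 4.30 (SE 0.464, adjusted p = 7.33e-04). Secreted plasma proteins fell in 3 and rose in 1 of 20 against 20 Gy (3 and 1 over the list alone), with a median of -0.53. As a list they had adjusted p = 0.0368, and adjusted p = 0.848 with an estimated correlation (range 0.0197 to 0.848). Against 30 Gy 4 fell and 1 rose (6 and 1 over the list alone), with a median of -0.46. The list as a whole had adjusted p = 0.0061, and adjusted p = 0.828 with an estimated correlation (range 0.00398 to 0.828). ALB fell by 1.87 (SE 0.269, adjusted p = 0.00268) and by 2.01 (SE 0.269, adjusted p = 0.00198), and the riser was APOA4, whose call was lost without 20Gy-1, 40Gy-2 and 40Gy-3 against 20 Gy (0.0604, 0.0541 and 0.0696, range 4.04e-04 to 0.0696) and without 30Gy-1 and 30Gy-2 against 30 Gy (0.0591 and 0.0579, range 2.33e-05 to 0.23).

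Acute phase genes rose in 4 of 11 against 20 Gy (4 over the list alone; median 1.27, adjusted p = 0.00268, and adjusted p = 0.848 with an estimated correlation, range 1.98e-04 to 0.848) and in 2 of 11 against 30 Gy (4), with a median of 1.28. Tested together, they had adjusted p = 0.0222, and adjusted p = 0.828 with an estimated correlation (range 0.00263 to 0.828). ITIH4 rose from 954.5 ± 380.3 and 1012 ± 422 to 9762 ± 5671 FPKM (3.17, SE 0.53, adjusted p = 0.00533, and 2.93, SE 0.53, adjusted p = 0.00859). Neutrophil markers rose in 4 of 9 in both comparisons (5 over the list alone in each; medians 0.82 and 0.72, adjusted p = 0.0234 and 0.0275, and adjusted p = 0.365 and 0.3 with an estimated correlation, 0.00181 to 0.365 and 0.00316 to 0.342 over alternatives). The calcium-binding neutrophil protein S100A12 rose by 2.64 (SE 0.382, adjusted p = 0.00273) and 2.77 (SE 0.382, adjusted p = 0.00226). T and NK cell markers fell in 3 of 15 in both (9 and 7 over the list alone; median -0.68 in each, adjusted p = 0.00384 and 0.00416, and adjusted p = 0.848 and 0.828 with an estimated correlation, 6.88e-05 to 0.848 and 6.4e-05 to 0.828 over alternatives). Stellate cell markers fell in 2 and 1 of 16 (2 and 0 over the list alone; medians -0.75 and -0.64, adjusted p = 0.0112 and 0.0222, and adjusted p = 0.848 and 0.828 with an estimated correlation, 2.24e-04 to 0.848 and 4.91e-04 to 0.828 over alternatives).

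Against 30 Gy alone, fatty acid oxidation genes fell in 5 of 20 (6 over the list alone; median -0.36, adjusted p = 0.0222, and adjusted p = 0.3 with an estimated correlation, range 6.01e-04 to 0.3), HADH among them (-1.16, SE 0.2, adjusted p = 0.00698). Erythroid genes fell in 2 of 4 (2 over the list alone), with a median of -1.27. Camera gave this list adjusted p = 0.0394, and adjusted p = 0.828 with an estimated correlation (range 0.0141 to 0.828). Immediate early genes rose in 1 of 17 (1 over the list alone), with a median of 0.64. Taken as 1 list, they had adjusted p = 0.0475, and adjusted p = 0.919 with an estimated correlation (range 6.2e-05 to 0.919). Against 20 Gy, calls of lists were lost without 20Gy-2 for plasma proteins, neutrophils and stellate cells (0.0675, 0.0595 and 0.0595), without 20Gy-3 and 40Gy-2 for plasma proteins (0.0949 and 0.083), without 40Gy-1 for neutrophils (0.17) and without 40Gy-3 for stellate cells (0.052). Against 30 Gy they were lost without 40Gy-1 for fatty acid oxidation, neutrophils and erythroid genes (0.0545, 0.16 and 0.0955), without 40Gy-2 (0.0621), with median-of-ratios scaling (0.0512) and with quantile normalization (0.0622) for erythroid genes, without 40Gy-3 for acute phase, stellate cells and erythroid genes (0.119, 0.127 and 0.0647), and without 30Gy-3 for acute phase genes (0.0519). Immediate early genes lost theirs without control-1, control-2, 30Gy-1, 30Gy-2, 40Gy-1, 40Gy-2 and 40Gy-3 (0.0637, 0.0589, 0.236, 0.22, 0.118, 0.0621 and 0.0616). THRSP was lost without 20Gy-1, 20Gy-2, 20Gy-3, 40Gy-2 and 40Gy-3 against 20 Gy (0.076, 0.0536, 0.078, 0.102 and 0.097, range 2.26e-05 to 0.164) and without 30Gy-1, 30Gy-2, 40Gy-2 and 40Gy-3 against 30 Gy (0.0665, 0.0665, 0.0861 and 0.064, range 3.17e-06 to 0.407).

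MT3 passed in both comparisons but was lost even without other groups' libraries. Against 20 Gy it was lost without 20Gy-1, 20Gy-2, 20Gy-3, 30Gy-1, 30Gy-2, 40Gy-2 and 40Gy-3 (0.102, 0.0571, 0.092, 0.0521, 0.0514, 0.124 and 0.113, range 6.51e-08 to 0.187). Against 30 Gy it was lost without control-1, control-2, 20Gy-1, 20Gy-3, 30Gy-1, 30Gy-2, 30Gy-3, 40Gy-2 and 40Gy-3 (0.0556, 0.0557, 0.0569, 0.0552, 0.101, 0.099, 0.0904, 0.152 and 0.111, range 6.51e-08 to 0.493). The 1748 genes against 20 Gy were 485, 602, 572 and 671 without 20Gy-1, 20Gy-3, 40Gy-2 and 40Gy-3, and 4174 without 40Gy-1. The 1417 genes against 30 Gy were 524, 533, 680, 466 and 757 without 30Gy-1, 30Gy-2, 30Gy-3, 40Gy-2 and 40Gy-3, and 3815 without 40Gy-1. With the 30 Gy pair averaged the counts were 1264 and 532, without 20Gy-3 and 30Gy-3 they were 538 and 395, with both 145 and 1, and with only the groups compared 536 and 512. With both, calls against 30 Gy were lost for SULT1A3 (0.0636), GLOD5 (0.133), MT1X (0.164), SCNN1B (0.162), CBR2 (0.147), EXTL1 (0.177) and IDI1 (0.193), each the highest over its alternatives, where the lowest lay between 1.41e-07 and 2.98e-06. Those of MVK (0.268), ALB (0.304), PNPLA3 (0.0619), ITIH4 (0.39), S100A12 (0.23) and HADH (0.363) were lost likewise (lowest 1.76e-07 to 3.1e-05). Against 20 Gy MVK (0.0537), ALB (0.0918), ITIH4 (0.083) and S100A12 (0.058) were lost, with lowest values of 2.63e-07 to 7.64e-06.

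In a linear trend over dose, 749 of 11526 genes changed (370 rose, 379 fell), but 0 between 30 and 20 Gy. SULT1A3 and GLOD5 rose by 3.06 per 10 Gy (SE 0.566 and 0.55, adjusted p = 0.037 each), MT1X by 2.78 (SE 0.539, adjusted p = 0.039) and SCNN1B by 2.02 (SE 0.422, adjusted p = 0.0408). FSTL3, a secreted inhibitor of activin, which overlaps PRSS57, was at 11.6 ± 5.11, 12.2 ± 5.1 and 128 ± 21.99 FPKM and rose by 1.71 per 10 Gy (SE 0.313, adjusted p = 0.037). CBR2 fell by 3.36 (SE 0.51, adjusted p = 0.037), EXTL1 by 2.76 (SE 0.557, adjusted p = 0.0406), CXCL9 by 2.56 (SE 0.497, adjusted p = 0.039) and IDI1 by 2.39 (SE 0.582, adjusted p = 0.0459). SERPINA6, the carrier of corticosteroids in blood, was at 129 ± 7.7, 143 ± 0.58 and 9.39 ± 12.3 FPKM and fell by 2.18 per 10 Gy (SE 0.528, adjusted p = 0.0458). Cholesterol synthesis genes fell in 8 of 20 (19 over the list alone; median -1.05, adjusted p = 1.93e-10), lipogenesis genes in 6 of 16 (11; median -1.02, adjusted p = 1.36e-06), T and NK cell markers in 1 of 15 (4; median -0.34, adjusted p = 0.00429), stellate cell markers in 2 of 16 (4; median -0.37, adjusted p = 0.00448) and plasma proteins in 1 of 20 (0; median -0.27, adjusted p = 0.0486). Acute phase genes rose in 4 of 11 (4 over the list alone; median 0.64, adjusted p = 0.0014), neutrophil markers in 3 of 8 (5; median 0.53, adjusted p = 0.0486) and macrophage markers in 1 of 18 (4; median 0.22, adjusted p = 0.0486), the last through GPNMB (1.58, SE 0.268, adjusted p = 0.037). With an estimated correlation the adjusted p was 0.813 for macrophages and 0.734 for the other 7 lists, the highest over alternatives, where the lowest were 1.09e-10, 5.45e-08, 2.43e-04, 1.49e-04, 0.021, 1.49e-04, 0.0178 and 0.00509 in the order given.

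The named trend calls lay near the threshold. 30 Gy, the middle dose, does not enter the slope: a step at 40 Gy gives one. The number of genes called was 0 without 20Gy-1, 20Gy-3, 30Gy-1, 30Gy-2, 40Gy-2 or 40Gy-3, and 1523, 1139 and 2267 without 20Gy-2, 30Gy-3 and 40Gy-1. It was 0 with the 30 Gy pair averaged, without 20Gy-3 and 30Gy-3, and with both. Each of the 10 named genes was lost in those 6 libraries' absence, with adjusted p of 0.11, 0.0821 to 0.092, 0.0528 to 0.0589, 0.0532 to 0.0605, 0.138 to 0.151 and 0.153 to 0.172 (0.00796 to 0.172 over all their alternatives). Plasma proteins lost their call without 20Gy-2, 20Gy-3, 30Gy-3, 40Gy-1, 40Gy-2 and 40Gy-3 (0.0639, 0.0756, 0.0506, 0.0696, 0.161 and 0.0512). Neutrophils lost theirs without 20Gy-2, 40Gy-1 and 40Gy-3 (0.088, 0.27 and 0.0501). Macrophages lost theirs without 20Gy-1, 20Gy-3 and 40Gy-1 (0.126, 0.127 and 0.296).

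Any difference among the 4 groups was found for 1611 of 11644 genes. The count was 805, 1018, 830, 855, 625, 818, 997 and 953 without 20Gy-1, 20Gy-3, 30Gy-1, 30Gy-2, 40Gy-2, 40Gy-3, control-1 and control-2, and 4156 without 40Gy-1. It was 850 with the 30 Gy pair averaged, 589 without 20Gy-3 and 30Gy-3, and 95 with both.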

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

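The opposite changes described here, the tests of scaling, of the fasting genes and of the stellate markers in 40Gy-1, and all tests of the library sets were chosen after the results were seen. The tests of vessel and bile duct markers and the other splits of the libraries were fixed earlier.

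The genes CBR2, CUX2, PER2 and ENSSSCG00000003006 were called in opposite directions at 20 and at 40 Gy against control, and so differed between 40 and 20 Gy. They were picked for opposite calls against the same controls, so a difference between the doses follows from the choice and its p-values add no support. CBR2, a carbonyl reductase that overlaps LOC102160997, was at 341 ± 341 FPKM in control, 3393 ± 1155 at 20 Gy and 33.9 ± 19.6 at 40 Gy, a log2 difference of -6.72 between the doses (SE 0.644, limma adjusted p = 4.08e-04). The clock gene PER2, a repressor in the daily feedback loop, was at 5.11 ± 3.12, 17.6 ± 2.7 and 1.17 ± 0.217 FPKM (-3.09, SE 0.268, adjusted p = 3.01e-04). The transcription factor CUX2 (-2.66, adjusted p = 8.75e-05) and the unnamed ENSSSCG00000003006 (-4.53, adjusted p = 3.08e-04) went the same way. The groups hold at most 3 libraries, so no library was tested as an outlier within its group.

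Higher lipogenesis genes with lower fatty acid oxidation genes at 20 and 30 Gy were weighed against feeding state and scaling. The FPKM scaling, with a few genes taking most of the FPKM, was argued against: 8 of the 8 lipogenesis genes called at 20 Gy stayed called after quantile normalization. Control livers sampled in a more fasted state stay open: the higher of the medians of 16 fasting-induced genes at 20 and 30 Gy was 0.33, where this explanation needs values below -0.5. That median came from 20 Gy, with quartiles of -1.21 and 0.66, and the median at 30 Gy was -0.41, so members went both ways and the test decides nothing, although its bound was met. The libraries split as well, along the sets described next: PCK1 was at 1639, 1599 and 1614 FPKM in 20Gy-1, 20Gy-3 and 30Gy-3, at 102, 96.4 and 94.5 in 20Gy-2, 30Gy-1 and 30Gy-2, and at 1550 and 1401 in control. The dose medians mix these sets in unequal parts. The spread was taken into account only after the value had been seen. Without the 10 genes shared with the fatty acid oxidation and gluconeogenesis lists, the medians were 0.55 at 20 Gy and -0.16 at 30 Gy. An effect of irradiation, of the 35 days between the groups, or of feeding may each underlie the pattern, and the design confounds them.

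The 20 and 30 Gy libraries fell into sets that cross the dose labels, with 20Gy-1, 20Gy-3 and 30Gy-3 on one side and 30Gy-1, 30Gy-2 and 20Gy-2 on the other. Exchanged labels of 20Gy-2 and 30Gy-3 stay open: both lay nearer to the other group than to their own, by 0.205 and 0.257 in spread, but this restates the pattern. An exchange as the whole cause of the near-identical pairs stays open. They had 0.231 and 0.14 of the lowest other spread in their set, but were picked for low spread. Near-identical pairs drawn from the same animal or RNA stay open too, since the pairs were picked for the low spread (at most 0.058 among highly expressed genes). Genes that respond to feeding split along the sets: besides PCK1, G6PC1 was at 1009, 958 and 954 FPKM in the first set and 135, 129 and 128 in the second, and IGFBP1 at 781, 714 and 706 against 38.5, 36.1 and 32.9. PPP1R3C went the other way, at 1.98, 2.05 and 2.13 against 44.3, 48.6 and 50.4, and CPT1A did not split. A difference in feeding or in the time of sampling between the sets therefore stays open, as the sets were defined from the same data and the labels give neither.

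Extracellular matrix genes were higher in 40Gy-1 than in 40Gy-2 and 40Gy-3 in 24 of 26 members, with a median log2 difference of 2. A larger share of stellate cells and myofibroblasts in 40Gy-1 fits, as their markers outside the matrix list had a median of 1.29. Macrophage markers (1.31) and T and NK cell markers (0.88) were higher as well, and sinusoidal endothelium markers lower (-0.5). Vessels or connective tissue of another kind stay open, with a lower median of 0.04 over 5 bile duct genes and 0.62 over 16 vascular genes. Feeding-responsive genes parted 40Gy-1 from 40Gy-2 and 40Gy-3 too, with PCK1 at 303 against 1866 and 1898 FPKM, IGFBP1 at 102.5 against 1074 and 946 and TAT at 171.5 against 2427 and 2026, so a difference in feeding or time of sampling stays open here as well. A biological difference between livers at 40 Gy was not tested, since the pattern is in 1 library.

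With the libraries split in other ways, the 40 against 30 Gy and 40 against 20 Gy counts were each the largest of 10 splits (1 of 10 in both, the others giving 0 genes), where 10 splits cannot give a share under 0.05. For 30 against 20 Gy the real count was 0, which any split reaches, so that 10 of 10 says nothing. There, 20Gy-1, 20Gy-3 and 30Gy-3 against the rest gave 1693 genes, which restates the structure of the samples described above and adds no support. For the trend, 2 of 100 splits gave at least 749 genes, the real one included, and the highest other gave 1021.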

How the results depend on the processing

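The near-identical pairs were handled after the data had been seen, and all other alternatives were fixed beforehand. Over all alternatives, named or example genes kept direction and side of the threshold in 4804 cases, were weaker in 1325, stronger in 9 and reversed in 4. Lists were the same in 1588, weaker in 223 and reversed in 20, and 131 counts stayed within 1.5 times and 115 moved. Estimated correlations lost 65 list calls, fry 39, quality weights 10, quantile normalization 4 and median-of-ratios scaling 1. Pseudocounts 0.1 and 0.01 lost 5 and 8, a mean of at least 5 FPKM 6, and settings for near-identical libraries 2, 7 and 7. The trend and the test of any difference have no fit of their own groups. Except where stated, the cause was not tested.

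Counts follow in the order 20 Gy, 30 Gy, 40 Gy and irradiated against control, 40 against 30 Gy, 40 against 20 Gy, trend, any difference and genes called at all 3 doses. With 30Gy-1 and 30Gy-2 averaged they were 295, 130, 548, 337, 532, 1264, 0, 850 and 59. Without 20Gy-3 and 30Gy-3 they were 206, 126, 551, 290, 395, 538, 0, 589 and 53, and with both 59, 8, 123, 42, 1, 145, 0, 95 and 6, while 30 against 20 Gy gave 2 and 1. Sample quality weights gave 3091, 1609, 3138, 1313, 6717, 6679, 3718, 9105 and 438. They gave 5688 for 30 against 20 Gy, where 20Gy-2 and 30Gy-3 had low weights (0.316 and 0.34). With only the groups compared, 40 Gy against control gave 31, 40 against 30 Gy 512, 40 against 20 Gy 536 and the overlap 7. A mean of at least 5 FPKM gave 222 at 30 Gy and 1067 for any difference, by testing fewer genes. An absolute log2 change of at least 1 gave 319 for irradiated liver, 784, 899 and 148 for 40 against 30 Gy, 40 against 20 Gy and the trend, by its own construction. Leaving out 1 library at a time gave 118 to 1644, 75 to 1110, 224 to 2655, 80 to 1416, 466 to 3815, 485 to 4174, 0 to 2267, 625 to 4156 and 27 to 374, and 0 to 3 for 30 against 20 Gy, where a lone control is assumed to vary like the other groups.

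The replicate numbers do not pair the libraries: 15 pairs sharing a number had correlations of -0.616 to 0.645, 7 of them above 0.1, and 5 of 11 libraries correlated best with their own number. With the number as a block the trend gave 0 genes in place of 749 and every other count stayed within 1.5 times. Of the list calls 4 were lost: complement at 20 Gy (0.14), acute phase at 40 Gy (0.0591), and plasma proteins (0.062) and neutrophils (0.0641) in the trend, with ranges over alternatives of 2.35e-04 to 0.751, 0.00102 to 0.885, 0.021 to 0.734 and 0.0178 to 0.734. The ferroptosis lists were called nowhere, so their reversals are changes of sign near 0. Suppressors reversed with the block (adjusted p = 0.763, 0.93, 0.873 and 0.874 at 20, 30 and 40 Gy and in irradiated liver). At 20 Gy they reversed without a filter (0.973), with pseudocount 0.01 (0.995), without 20Gy-3 and 30Gy-3 (0.915), with the 30 Gy pair averaged as well (0.962), and without 20Gy-3 (0.84), control-2 (0.887) and 40Gy-1 (0.999), in a range of 0.736 to 1 over single libraries. At 40 Gy (0.653 to 0.954) and in irradiated liver (0.909 to 0.988) they reversed without single libraries, in ranges of 0.653 to 0.954 and 0.755 to 0.988 over all of these, and in irradiated liver without 20Gy-3 and 30Gy-3 (0.987). Drivers at 20 Gy reversed with a mean of at least 5 FPKM (0.919), without 20Gy-3 and 30Gy-3 (0.994) and without control-2 (0.887), in a range of 0.62 to 0.887 over single libraries. In irradiated liver MDM2 turned to -0.02 with quality weights and -0.03 and -0.02 without control-1 and 40Gy-1 (-0.03 to 0.06 over single libraries), and TFRC to -0.4 without control-2.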

Other observations

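The genes in this part were chosen after their values were seen. Of 17 gluconeogenesis genes 0 rose and 2 fell at each dose, and of 17 clock genes 1 rose and 1 fell at 20 and 30 Gy and 2 fell at 40 Gy, while neither list was called. Pyruvate carboxylase, PC, was at 313 ± 36.1 FPKM in control and 105 ± 11.9, 86.1 ± 8.91 and 131 ± 26.9 at 20, 30 and 40 Gy, and fell at each dose (log2 -1.57, -1.89 and -1.26, SE 0.222, limma adjusted p = 0.0042, 0.00214 and 0.0098). The bisphosphatase FBP1 fell as well (-1.70, -1.39 and -1.20, SE 0.32, adjusted p = 0.0168, 0.0478 and 0.0496). The clock repressor NR1D1 fell from 5.69 ± 1.53 to 1.1 ± 0.169, 0.843 ± 0.151 and 1.7 ± 1.08 (-1.65, -1.87 and -1.36, SE 0.278, adjusted p = 0.00998, 0.00649 and 0.0182), whereas PER2 rose at 20 and 30 Gy and fell at 40 Gy (1.70, 1.45 and -1.40, SE 0.3, adjusted p = 0.0127, 0.033 and 0.0222). Alpha-fetoprotein, AFP, rose at 20 and 30 Gy as 1 of 6 fetal liver genes (2.63 and 2.81, SE 0.233, adjusted p = 4.2e-04 and 3.04e-04).

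Of 7 B and plasma cell genes 2 rose and 1 fell at 40 Gy: JCHAIN (2.56, SE 0.256, adjusted p = 0.00109), MZB1 (1.94, SE 0.354, adjusted p = 0.0118) and CD79A (-0.99, SE 0.195, adjusted p = 0.0159). These genes were not refitted under the alternatives. In a check for mixed-up samples, which had 1 gene to go by, 1 of 11 libraries did not match its group.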
